A study of Homo sapiens with 18 samples.

How the data were processed

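RNA was measured in THP1-Dual cells, wild type or STING knockout, in 6 groups of 3 libraries. Per the labels' protocols, cells were held for 1 h in DMSO or in H151 at 500 ng/mL and then for 8 h in medium or in TL8 at 10 µg/mL, and libraries were made from 100 ng of RNA with a directional NEBNext Ultra II kit. The protocol text leaves open whether poly(A) selection or removal of ribosomal RNA was used, which sets how transcripts without a poly(A) tail, such as those of replication-dependent histone genes, are seen.

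The authors deposited 1 table of 58884 genes for all 18 libraries. Per the file headers its values are normalized counts, a score that the authors made by scaling and rounded to whole numbers before deposit. They are not treated as raw counts. Trim Galore, cutadapt, STAR and DESeq2 are named, per the submitters' processing notes, without versions or roles. The genome build and annotation are not given in the sources used here. Of the gene identifiers, 58611 were also in GENCODE 29 on GRCh38, and 48209 of these (82.25%) had the identical chromosome, start and end there, while 273 identifiers were not in that release. Coordinates are printed as the deposited table gives them. A further 149 gene symbols occurred on more than 1 line of the table. The same table gives the authors' log2 fold changes and adjusted p-values for 5 pairs of groups, per the file headers. Only the counts of genes at a false discovery rate of 0.05 are quoted from those, as the authors' deposited table. All columns of per-sample values could be assigned to a sample.

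Groups were taken from the description of each sample, which is also the column name and the name the authors' comparisons use. For 6 wild-type samples the title and the treatment label say otherwise, and exchange the group with DMSO and TL8 and the group with H151 and medium. The exchange was run as an alternative. The title of 1 further sample leaves out TL8, which its treatment label and description give. Nothing in the labels says whether the replicates of a group were separate cultures, or that a replicate number marks a shared day.

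The plan for raw counts was a quasi-likelihood test. Because the deposited values are normalized, the test named in the plan for that case was used, which is limma with a trend on log2(value + 1). The pseudocount of 1 shrinks the fold changes of low genes. Genes with a mean of at least 10 in at least 1 group were tested, 16375 in all, in a model with a coefficient for each of the 6 groups, so that all 18 libraries share an estimate of the spread with 12 residual and 20.52 total degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each comparison and called at 0.05, two-sided. There were 7 comparisons of a pair of groups and 2 interactions. The pairs were TL8 against medium in wild-type cells, in knockout cells and in wild-type cells with H151, knockout against wild type in medium and with TL8, and H151 against DMSO in medium and with TL8. The interactions were the difference of the TL8 response between knockout and wild type, and between H151 and DMSO.

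The comparisons, the test, the alternatives, the rule for naming genes and the groups were fixed before the data were examined. The genes named are of 3 kinds. The first is a fixed panel, STING (listed as TMEM173), TLR8, IFNB1, IFNL1, CXCL10, ISG15, IFIT1, MX1, RSAD2, TNF, IL6, IL1B, CXCL8 and NFKBIA. The next kind is the 6 largest rises and the 6 largest falls of a comparison among called genes with a mean of at least 100 in a compared group and, for a pair of groups, no overlap between replicates, without loci that carry only a clone name. The last is up to 4 members of each described list, the 3 called members with the largest change and the most expressed member that was not called. Not every gene these parts give is named. Genes outside the rule are marked as chosen after their values were seen.

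The 22 gene lists were written from general knowledge before the data were examined, with 590 entries of which 586 were found in the table. They cover type I and III interferon genes, interferon-stimulated genes, inflammatory cytokines and chemokines, NF-kappaB feedback and signalling, STING and cytosolic nucleic acid sensing, the endosomal Toll-like receptor pathway, antigen presentation, monocyte to macrophage markers, NRF2 oxidative stress, heat shock, the unfolded protein and integrated stress responses, cholesterol synthesis, liver X receptor targets, glycolysis, proliferation, p53 targets, ribosomal proteins, mitochondrially encoded genes, replication-dependent histones, and markers of lymphoid, epithelial and fibroblast, and erythroid and megakaryocyte cells. For each list the members called were counted over all genes and adjusted over the list alone. Each list was compared with all other tested genes by limma's camera with a preset correlation of 0.01, with p adjusted over the lists of a comparison, and again with the correlation estimated from the data.

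The deposited values sum to 22531043 to 26580125 per library. Whole reads could not be recovered, since the values are rounded, but whole numbers that a library skips or holds too often give the value of 1 read, between 0.823 and 1.22, and so an estimated 20790000 to 30042000 reads assigned to genes. The median standard error of a log2 fold change was 0.109 for a pair of groups and 0.154 for an interaction. The steps were tested on simulated data with seeded changes of 1.5-fold, 2-fold and 4-fold. All 6 groups were simulated from the wild-type DMSO medium means, and only genes above a minimum mean were changed. The figures thus do not cover genes that lie near the floor in some groups and high in others, such as CXCL10. For TL8 in wild-type cells (15756 genes) 80.6%, 97.01% and 100% of the changed genes were called, for the knockout interaction (15733 genes) 49.25%, 86.57% and 100%, and for the H151 interaction (15738 genes) 65.67%, 89.55% and 98.48%. Over all comparisons 4 to 19 unchanged genes were called.

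Alternatives were rescaling by the upper quartile, limma without trend, no filter, a minimum mean of 100, pseudocounts of 0.5 and 8, the replicate number as a block, groups from title and treatment labels, only the libraries of the groups compared, each library left out in turn, a minimum absolute log2 fold change of 1, and an estimated correlation in camera. Leaving out libraries 1 and 2 of the wild-type group with DMSO and medium together was added after seeing the data. It leaves 1 library in that group, so calls lost in that fit can come from the smaller number of samples. Genes that share reads with near-identical copies are uncertain, since how the counting treated such reads is not given in the sources used here. This covers ALPP and ALPG, RN7SL2, CCL3, the interferon alpha genes, the histone genes and the HLA genes. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.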

Results

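RNA sequencing was carried out on THP1-Dual cells, a human monocytic leukaemia line that carries a secreted alkaline phosphatase reporter for NF-kappaB and a luciferase reporter for interferon regulatory factors. Wild-type cells and cells with a knockout of STING, the endoplasmic reticulum adaptor of cytosolic DNA sensing, were compared. They were held for 1 h in the solvent DMSO or, for the wild type only, in 500 ng/mL of H151, a covalent inhibitor of STING. They were then held for 8 h in medium or in 10 µg/mL of TL8, taken from the series title to be a ligand of the endosomal receptor TLR8. This gave 6 groups of 3 libraries, 18 in all: wild type with DMSO and medium, wild type with DMSO and TL8, wild type with H151 and medium, wild type with H151 and TL8, knockout with DMSO and medium, and knockout with DMSO and TL8. The title of the series asks whether interferon production through TLR8 needs STING. The deposited values were normalized gene counts that summed to between 22531043 and 26580125 per library. The low values pointed to an estimated 20790000 to 30042000 reads assigned to genes. The groups follow the description and column names. The titles and treatment labels of 6 wild-type samples exchange the DMSO with TL8 group and the H151 with medium group, which would turn the direction of many wild-type results given here.

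The libraries separated by genotype along the first principal component, with 61.4% of the variance, and by TL8 along the next, with 21.3%. Pearson correlations between replicates, across genes, lay between 0.989 and 0.994. No library duplicated another. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. All fold changes are on the scale log2(normalized value + 1), which understates changes of low genes, and come with their standard error (SE) and a Benjamini-Hochberg adjusted p from limma. Of the 58884 genes listed, 16375 were tested.

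STING, listed as TMEM173 (ENSG00000184584, chromosome 5, 139475533 to 139482935 as the deposited table gives it), was the targeted gene and was measured in every group. It averaged 4913 ± 295 (SD, n = 3) in wild-type cells in medium, 3880 ± 128 with TL8, 5631 ± 56.3 with H151 in medium and 3946 ± 41.0 with H151 and TL8. In knockout cells it averaged 2711 ± 46.3 in medium and 2775 ± 287 with TL8. The knockout line thus held less STING transcript than the wild type, by a log2 fold change of -0.86 ± 0.06 in medium (limma adjusted p = 2.43e-10) and -0.49 ± 0.06 with TL8 (limma adjusted p = 7.72e-07). TL8 lowered it in wild-type cells (-0.34 ± 0.06, limma adjusted p = 0.000166), and this response differed from that of the knockout line by 0.37 ± 0.09 (limma adjusted p = 0.00476). The transcript was still present in the knockout line, so that the counts check the direction of the label and not the loss of the protein.

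TL8 raised interferon-stimulated genes, chemokines and NF-kappaB target genes in wild-type cells. CXCL10, a chemokine that attracts T cells, went from 0.333 ± 0.577 to 33196 ± 2554 (SD, n = 3), a log2 fold change of 14.68 ± 0.37 (limma adjusted p = 2.29e-18). IFIT1, an interferon-induced RNA-binding protein, rose from 32.7 ± 4.04 to 12434 ± 548 (log2 fold change 8.53 ± 0.22, limma adjusted p = 2.82e-18). The ubiquitin-like ISG15 rose from 418 ± 80.6 to 11973 ± 1433 (4.85 ± 0.14, limma adjusted p = 3.8e-17). All 58 measured interferon-stimulated genes of a list of 60 rose, and all 58 did so adjusted over the list alone. Their median log2 fold change was 4.69 (camera adjusted p = 1.1e-62 and, with an estimated correlation, adjusted p = 1.55e-05). The chemokine CXCL11, the GTPase GBP1 and IFI44L rose by log2 fold changes of 10.42 ± 0.20, 9.03 ± 0.59 and 8.96 ± 0.50, and the antiviral enzyme RSAD2 by 3.71 ± 0.45 (limma adjusted p from 3.15e-20 to 8.34e-07 among these 4).

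**Figure D1:**
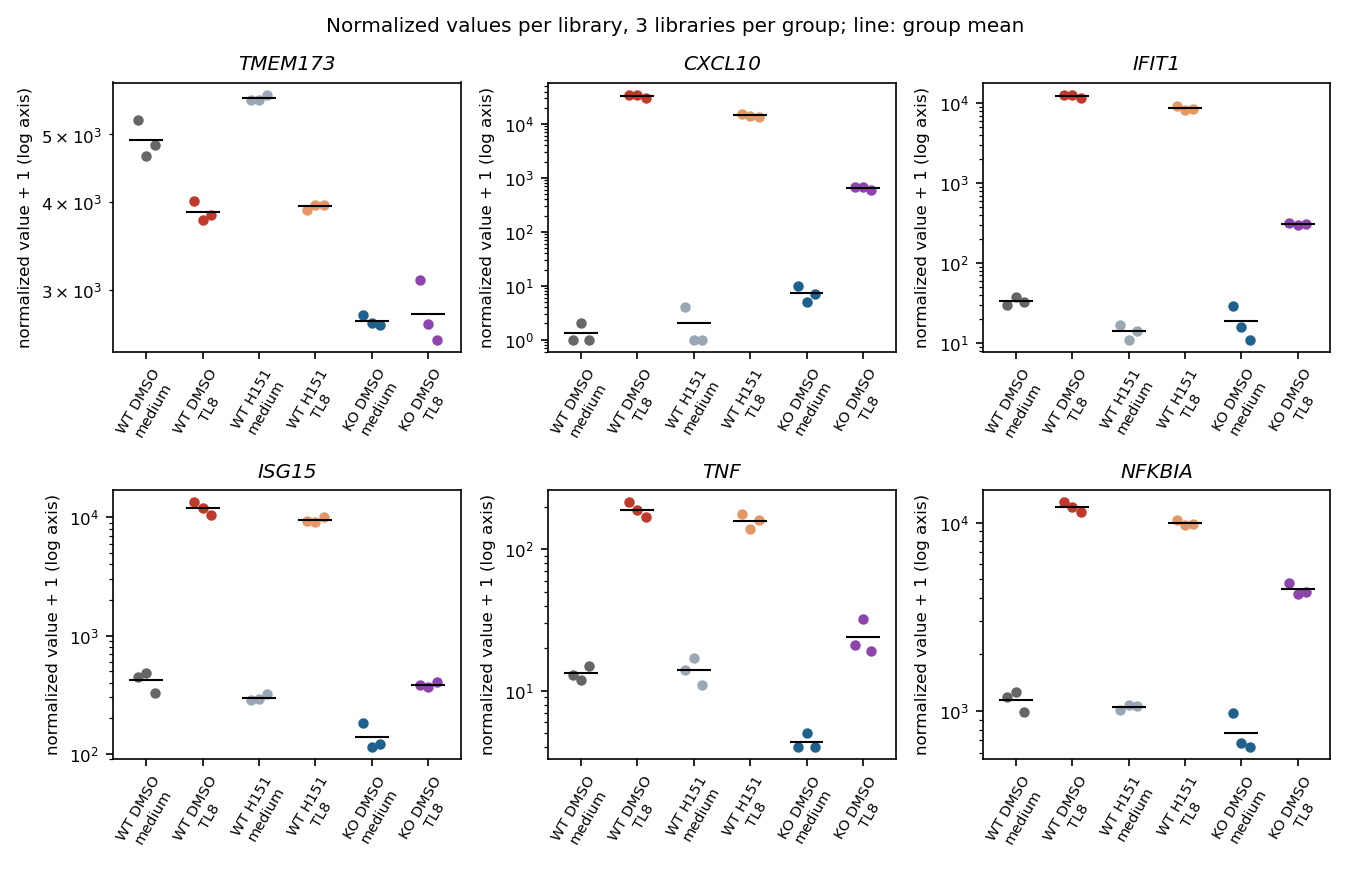
Normalized value + 1 per library (points, log axis) in the 6 groups, with 3 libraries each and a line at the group mean, for 6 genes. CXCL10 reached 33196 in wild-type cells with TL8, 14368 with H151 and TL8 and 648 in knockout cells with TL8, and TMEM173, the STING gene, stayed at 2711 and 2775 in the knockout groups.

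Inflammatory and NF-kappaB genes rose in the same cells. Of 28 measured inflammatory cytokine and chemokine genes, 24 rose, 1 fell and 3 did not pass (25 and 1 adjusted over the list alone), with a median log2 fold change of 3.33 (camera adjusted p = 1.76e-15). TNF rose by 3.84 ± 0.23, the precursor gene of interleukin-1 beta IL1B by 5.88 ± 0.31, the neutrophil chemokine gene CXCL8 by 5.48 ± 0.36 and the monocyte chemokine gene CCL2 by 8.40 ± 0.16, with limma adjusted p from 3.65e-11 to 2.14e-20. IL6, listed at 0 in every wild-type library in medium, had 16 ± 1.73 with TL8. CCL22 did not pass (0.07 ± 0.27, limma adjusted p = 0.853). Of 31 NF-kappaB feedback and signalling genes, 29 rose, 1 fell and 1 did not pass (30 and 1 adjusted over the list alone), with a median of 2.45 (camera adjusted p = 6.75e-24). The adhesion molecule ICAM1 rose by 7.14 ± 0.48. NFKBIA, the inhibitor that NF-kappaB itself induces, rose by 3.40 ± 0.11.

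Other groups rose by less. Of 22 antigen presentation genes, 17 rose and 5 did not pass (18 adjusted over the list alone; median 0.99, camera adjusted p = 1.79e-09), led by the peptide transporter gene TAP1 at 3.84 ± 0.07. HLA-DRB1 did not pass (-0.05 ± 0.10, limma adjusted p = 0.692). Of 25 genes of the unfolded protein and integrated stress responses, 21 rose, 1 fell and 3 did not pass (21 and 1 adjusted over the list alone; median 1.37, camera adjusted p = 1.73e-13). Among them were ATF3 at 2.58 ± 0.24 and the endoplasmic reticulum chaperone gene HYOU1 at 2.24 ± 0.10. Of 26 endosomal Toll-like receptor pathway genes, 16 rose, 2 fell and 8 did not pass (16 and 3 adjusted over the list alone; median 0.29, camera adjusted p = 0.000217). In this list TLR7 rose by 5.42 ± 0.43, the adaptor gene MYD88 by 2.65 ± 0.06, and TLR8 from 4.33 ± 1.53 to 38.0 ± 7.21 (2.89 ± 0.48, limma adjusted p = 4.59e-05). Among the largest falls were those of SERPINB2, a protease inhibitor of activated monocytes (-3.25 ± 0.08), METTL7A (-2.78 ± 0.16), the p38 kinase activator gene MAP2K6 (-2.51 ± 0.14) and the mTOR-binding DEPTOR (-2.18 ± 0.09), each with a limma adjusted p of 4.15e-12 or lower.

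With TL8, 7680 genes changed in wild-type cells, 3930 upward and 3750 downward. Of these, 1159 were at least 2-fold higher and 600 at least 2-fold lower. The authors' deposited table counts 8107 genes for the same pair of groups at a false discovery rate of 0.05. Rescaling every library by its upper quartile moved the median of all genes by -0.14 and the upward share among the genes called from 51.2% of 7680 to 31.9% of 8905, so that small changes of either sign depend on the scaling. Libraries 1 and 2 of the wild-type DMSO medium group had a higher ribosomal protein share (9.11% and 10.1%) than library 3 (7.62%) and the other wild-type libraries. Knockout libraries in medium had shares of 7.94% to 9.62%. Without libraries 1 and 2 the wild-type DMSO medium group holds 1 library. Fewer genes were then called, and the smaller number of samples is part of the cause.

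In STING knockout cells, TL8 still raised NF-kappaB genes and part of the interferon-stimulated genes. NFKBIA went from 767 ± 186 to 4416 ± 320 (SD, n = 3; log2 fold change 2.55 ± 0.11, limma adjusted p = 5.72e-13). TNFAIP3, a deubiquitinase that ends NF-kappaB signalling, rose from 379 ± 41.5 to 3796 ± 187 (3.33 ± 0.08, limma adjusted p = 1.15e-16), and TNF by 2.44 ± 0.23 (limma adjusted p = 8.9e-08). CXCL10 went from 6.33 ± 2.52 to 648 ± 47.3 (6.52 ± 0.37, limma adjusted p = 3.3e-11). IFIT1 went from 17.7 ± 9.29 to 308 ± 9 (4.17 ± 0.22, limma adjusted p = 8.38e-12) and ISG15 from 139 ± 38.6 to 384 ± 18.7 (1.496 ± 0.14, limma adjusted p = 1.37e-07). IFI44L, MX1 and RSAD2 did not pass, with log2 fold changes of 0.25 ± 0.50, -0.09 ± 0.17 and -0.23 ± 0.45 (limma adjusted p from 0.823 to 0.834). Without STINGKO_DMSO_medium library 1 or 3, IFI44L was at 1.03 (limma adjusted p = 0.0941) or -0.75 (limma adjusted p = 0.123), and MX1 was at 0.023 without library 3 (limma adjusted p = 0.969). RSAD2 stood at 26, 2 and 19 in the 3 libraries with TL8, and without library 2 its log2 fold change was 0.75 (limma adjusted p = 0.00184).

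Of the 58 measured interferon-stimulated genes, 44 rose in the knockout line, 1 fell and 13 did not pass (47 and 1 adjusted over the list alone), with a median log2 fold change of 1.03 (camera adjusted p = 1.41e-57 and, with an estimated correlation, adjusted p = 2.46e-05). Of 28 inflammatory genes, 19 rose, 1 fell and 8 did not pass (21 and 1 adjusted over the list alone; median 1.87, camera adjusted p = 2.1e-20), led by the chemokine gene CCL3 at 4.26 ± 0.50, with IL1B at 3.08 ± 0.31 and CXCL8 at 2.04 ± 0.36. Of 31 NF-kappaB genes, 20 rose, 1 fell and 10 did not pass (22 and 1 adjusted over the list alone; median 1.15, camera adjusted p = 2.52e-37), among them BCL3 at 3.77 ± 0.17 and the apoptosis inhibitor gene BIRC3 at 3.64 ± 0.28. The placental alkaline phosphatase gene ALPP and its near-identical neighbour ALPG rose by 3.89 ± 0.60 and 4.16 ± 0.74. Transcripts of the phosphatase reporter carried by the line stay open as a source of these values. Both genes are also uncertain since reads can be shared between them and since the knockout libraries in medium differed in both. Without STINGKO_DMSO_medium library 3 they rose by 2.63 and 2.63, and without library 1 by 4.92 and 5.40. The amino acid oxidase gene IL4I1 rose by 4.11 ± 0.42 and the sugar transporter gene SLC2A6 by 3.92 ± 0.16. MAP2K6 (-2.24 ± 0.14), METTL7A (-1.18 ± 0.16) and the receptor gene KIT (-1.10 ± 0.12) were among the largest falls, with limma adjusted p of 1.91e-05 or lower.

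In all, 1497 genes changed with TL8 in the knockout line, 931 upward and 566 downward. Of the genes that rose, 812 also rose in the wild type, where independent lists of these lengths would share 223.4, and 358 of those that fell also fell in the wild type, against 129.6. Of the 931 that rose, 244 were higher in the H151 medium group than in the DMSO medium group, against 145.7, and this is the group that the titles of 6 wild-type samples exchange with that of DMSO and TL8. With only the groups compared in the model, the count for TL8 in the knockout line was 767. The upward share was 62.2% and, after rescaling by the upper quartile, 45.6%.

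The difference between both TL8 responses was tested as an interaction. All 58 interferon-stimulated genes had a smaller response in the knockout line, and all 58 did so adjusted over the list alone, with a median difference of -3.26 in log2 fold change (camera adjusted p = 5.62e-80 and, with an estimated correlation, adjusted p = 4.08e-06). The difference was -8.16 ± 0.52 for CXCL10, -8.92 ± 0.83 for GBP1, -8.72 ± 0.71 for IFI44L, -4.37 ± 0.31 for IFIT1, -3.94 ± 0.64 for RSAD2, -3.35 ± 0.20 for ISG15 and -2.41 ± 0.24 for MX1 (limma adjusted p from 4.24e-11 to 9.81e-05 among these 7). The response of NFKBIA differed by less (-0.85 ± 0.16, limma adjusted p = 0.000456), as did that of TNF (-1.40 ± 0.32, limma adjusted p = 0.00289).

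Of 28 inflammatory genes, 20 responded less in the knockout line, 1 responded more and 7 did not pass (20 and 1 adjusted over the list alone; median -1.76, camera adjusted p = 7.21e-11 and, with an estimated correlation, adjusted p = 0.00807), with CCL2 at -6.53 ± 0.22, CXCL8 at -3.44 ± 0.50 and IL1B at -2.80 ± 0.44. In medium CXCL8 stood at 368, 154 and 61 in the knockout libraries and at 24, 25 and 23 in the wild type. With TL8 it was at 582, 584 and 722 against 1053, 1196 and 1108. IL1B stood at 140, 64 and 35 against 30, 20 and 26 in medium. Part of both differences thus came from higher knockout values in medium, which varied between libraries. Of 31 NF-kappaB genes, 23 responded less and 8 did not pass (24 adjusted over the list alone; median -0.94, camera adjusted p = 1.38e-15 and, with an estimated correlation, adjusted p = 0.00663), with TNFAIP6 at -7.14 ± 1.00 and ICAM1 at -4.37 ± 0.68. The knockout libraries in medium varied in both, at 15, 6 and 0 for TNFAIP6 and at 60, 36 and 5 for ICAM1. Of 22 antigen presentation genes, 13 responded less and 9 did not pass (14 adjusted over the list alone; median -0.79, camera adjusted p = 3.89e-08), with TAP1 at -2.95 ± 0.10 and HLA-F at -2.98 ± 0.52. Of 25 unfolded protein and integrated stress response genes, 18 responded less, 1 responded more and 6 did not pass (19 and 1 adjusted over the list alone; median -1.07, camera adjusted p = 1.96e-13), with HYOU1 at -1.71 ± 0.13 and ATF3 at -1.95 ± 0.35, while ATF4 did not pass (-0.20 ± 0.10, limma adjusted p = 0.159). Of 26 endosomal Toll-like receptor pathway genes, 8 responded less, 2 responded more and 16 did not pass (11 and 2 adjusted over the list alone; median -0.21, camera adjusted p = 0.00573), with MYD88 at -2.12 ± 0.08 and TLR8 not past the test (-1.05 ± 0.68, limma adjusted p = 0.277, but 0.00334 with a pseudocount of 8).

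**Figure D2:**
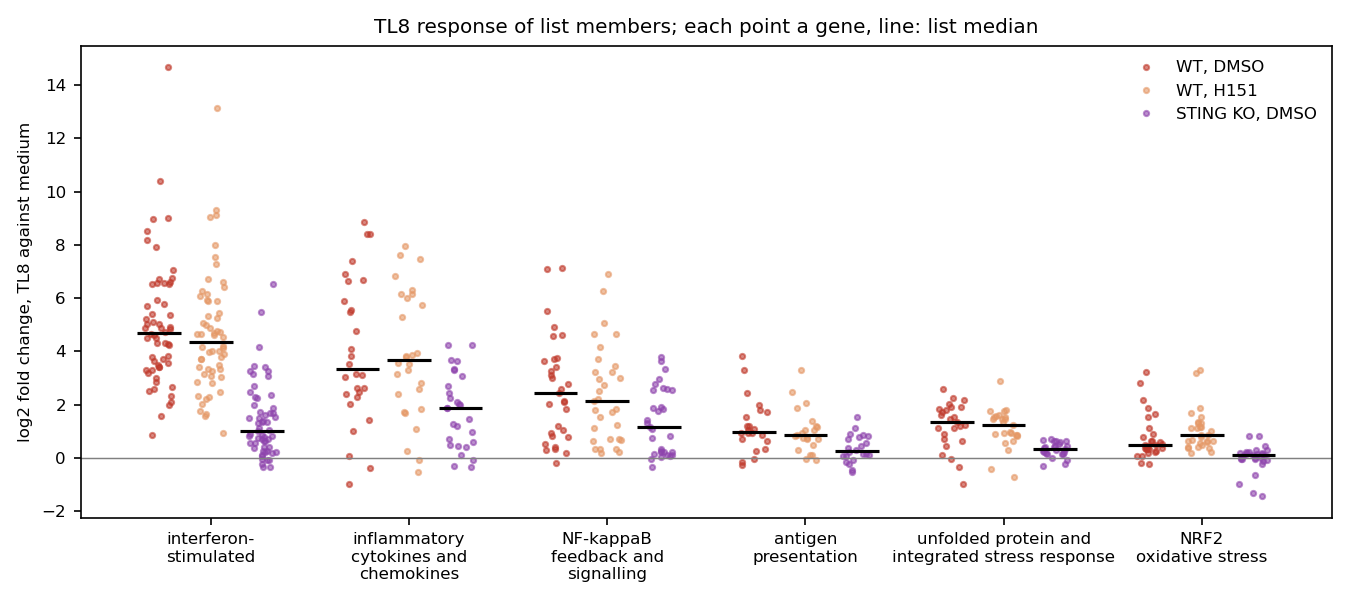
TL8 response (log2 fold change against medium, vertical axis) of the measured members of 6 gene lists, with 1 point per gene and a line at the list median, in wild-type cells with DMSO, wild-type cells with H151 and knockout cells with DMSO. The medians of the interferon-stimulated genes were 4.69, 4.36 and 1.03.

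VCAM1, the vascular adhesion molecule, had 931 ± 72.6 (SD, n = 3) in wild-type cells with TL8 and was listed at 0 in every knockout library with TL8, and the chemokine gene CCL8 had 470 ± 71.7 against 8.00 ± 3.00. Of 600 genes that fell at least 2-fold with TL8 in the wild type, 265 (44.2%) fell less in the knockout line. Among them were SERPINB2 (difference 2.75 ± 0.11), the Wnt ligand gene WNT7B (1.87 ± 0.19), DEPTOR (1.77 ± 0.12) and the transcription factor gene NFE2 (1.64 ± 0.14), with limma adjusted p of 1.98e-07 or lower. The interaction called 4023 genes, 1705 of them upward and 2318 downward. Among the 1159 genes that rose at least 2-fold in the wild type, 917 (79.1%) had a smaller response in the knockout line. The same wild-type libraries enter both lists of each of these overlaps, so part of each may come from those libraries, and no value without an effect was computed for them. Rescaling by the upper quartile moved the upward share among the genes called from 42.4% of 4023 to 61.1% of 4824, and leaving out libraries 1 and 2 of the wild-type DMSO medium group left 2190 genes.

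The type I and III interferon genes themselves were listed near the floor. None of the 21 genes of this list reached the mean of 10 required for the test. A value of 0 need not mean that a transcript was absent. IRF9, TREX1 and HSPA1B were also listed at 0 in all 18 libraries, and the treatment of reads shared between similar genes is not given. RNA was taken only after 8 h. IFNB1, the interferon beta gene (ENSG00000171855, chromosome 9, 21077104 to 21077942), was at 8, 4 and 7 in the wild-type libraries with TL8, at 1, 2 and 2 with H151 and TL8, and at 1, 0 and 1 in the knockout libraries with TL8. The wild-type libraries in medium had 1, 2 and 0. Each of the 3 wild-type libraries with TL8 lay above each of the other 15 libraries. IFNL1 was at 1, 1 and 0 in the wild type with TL8 and listed at 0 elsewhere.

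H151 tests the part of STING with a drug in the wild-type line. With H151, TL8 still raised all 58 measured interferon-stimulated genes (58 adjusted over the list alone), with a median log2 fold change of 4.36 (camera adjusted p = 2.3e-75 and, with an estimated correlation, adjusted p = 5.68e-06). CXCL10 went from 1.00 ± 1.73 to 14368 ± 939 (SD, n = 3; 13.14 ± 0.37, limma adjusted p = 2.27e-17) and IFIT1 from 13 ± 3 to 8720 ± 571 (9.30 ± 0.22, limma adjusted p = 7.97e-19). The antiviral gene TRIM22 went from 26 ± 2.65 to 6913 ± 113 (8.01 ± 0.14, limma adjusted p = 1.29e-20). Of 28 inflammatory genes, 25 rose, 1 fell and 2 did not pass (25 and 1 adjusted over the list alone; median 3.69, camera adjusted p = 8.81e-20). Of 31 NF-kappaB genes, 29 rose and 2 did not pass (31 adjusted over the list alone; median 2.12, camera adjusted p = 1.1e-29). SERPINB2 (-2.51 ± 0.08), the telomerase gene TERT (-2.45 ± 0.22) and MAP2K6 (-2.41 ± 0.14) were among the largest falls (limma adjusted p of 9.45e-09 or lower). In all, 5953 genes changed, 3101 upward and 2852 downward. Rescaling by the upper quartile moved the median of all genes by -0.12 and the upward share from 52.1% to 32.2%.

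The interaction of TL8 with H151 was small beside that with the knockout. Of the 58 interferon-stimulated genes, 5 had a smaller response with H151 and 53 did not pass (16 smaller adjusted over the list alone). The median difference was -0.27 (camera adjusted p = 1.09e-07), and this call was lost with an estimated correlation (adjusted p = 0.172). SAMD9L, a translation repressor (-0.86 ± 0.13, limma adjusted p = 0.00219), and GBP4 (-0.85 ± 0.14, limma adjusted p = 0.0092) were among the 5. In medium, SAMD9L stood at 1393, 1401 and 1361 with H151 against 797, 743 and 993 with DMSO. With TL8 it was at 24806, 22723 and 20658 against 23160, 25883 and 25607. GBP4 stood at 145, 136 and 116 against 81, 78 and 90 in medium. With TL8 it was at 3186, 3021 and 3004 against 3305, 3641 and 3571. Part of the difference of both genes thus came from higher medium values with H151. Without WT_DMSO_medium libraries 1 and 2 together, both lost their call (limma adjusted p of 0.0635 and 0.143). The differences of CXCL10 (-1.54 ± 0.52), IFIT1 (0.77 ± 0.31) and ISG15 (0.14 ± 0.20) did not pass (limma adjusted p of 0.157, 0.217 and 0.752). Neither did those of TNF (-0.31 ± 0.32, limma adjusted p = 0.647) and NFKBIA (-0.16 ± 0.16, limma adjusted p = 0.643). With a pseudocount of 8 the difference of CXCL10 passed (-1.30, limma adjusted p = 0.000654), as did that of IFIT1 with only the 4 groups compared in the model (limma adjusted p = 0.0257). The lectin receptor gene CD209 (-1.28 ± 0.16, limma adjusted p = 0.000458) and the complement receptor gene C3AR1 (-1.15 ± 0.13, limma adjusted p = 0.000238) also responded less. Both were lower with H151 under TL8, but also higher with H151 in medium. There CD209 stood at 188, 196 and 182 against 128, 133 and 154, and C3AR1 at 128, 138 and 143 against 79, 73 and 68. The arrestin-domain gene ARRDC4 (0.80 ± 0.11, limma adjusted p = 0.000875) and SERPINB2 (0.74 ± 0.11, limma adjusted p = 0.00318) had positive differences. The call of SERPINB2 was lost without WT_DMSO_medium libraries 1 and 2 together, which leaves 1 library in that group. In medium SERPINB2 stood at 889, 996 and 965 with H151 against 1763, 1920 and 1630 with DMSO. With TL8 it was at 161, 155 and 181 against 195, 168 and 193. Its positive difference thus came from lower medium values with H151.

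CXCL11 passed (-1.31 ± 0.28, limma adjusted p = 0.0366), but not after the omission of any 1 of 9 of the 12 libraries (limma adjusted p from 0.0869 to 0.143). The 3 whose omission kept it were WT_DMSO_medium libraries 1 and 3 and WT_H151_medium library 2. GBP2 (-0.99 ± 0.20, limma adjusted p = 0.0272) kept its call only without WT_DMSO_medium library 3 (the other 11 omissions gave 0.0516 to 0.115). In medium GBP2 stood at 69, 77 and 77 with H151 against 33, 33 and 35 with DMSO. With TL8 it was at 1133, 1091 and 986 against 967, 1049 and 929. Its smaller response thus came from higher medium values with H151. RN7SL2, an RNA of the signal recognition particle with many near-identical copies and so uncertain (-2.81 ± 0.62, limma adjusted p = 0.0375), kept its call only without WT_DMSO_medium library 2 or 3 (the other 10 omissions gave 0.0649 to 0.128). Of 29 NRF2 oxidative stress genes, 2 had a larger TL8 response with H151 and 27 did not pass (9 larger and 1 smaller adjusted over the list alone; median 0.31, camera adjusted p = 4.06e-06, lost with an estimated correlation at adjusted p = 0.453). The cystine transporter gene SLC7A11 was one of them (0.69 ± 0.13, limma adjusted p = 0.0152) and lost its call without WT_H151_medium library 1 (0.0516) or 3 (0.0552) or WT_H151_TL8 library 1 (0.0518) or 2 (0.0619). Ribosomal protein genes had a median of 0.29 with 0 of 35 past the test (0 adjusted over the list alone; camera adjusted p = 4.63e-11, lost with an estimated correlation at adjusted p = 0.453). The WT_DMSO_medium libraries that enter it differed in the share of these genes, at 9.11%, 10.1% and 7.62% in libraries 1, 2 and 3.

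In total the H151 interaction called 116 genes, 31 upward and 85 downward. Of the 1159 genes that rose at least 2-fold with TL8 in the wild type, 65 responded less with H151. The same wild-type DMSO libraries enter both lists, so part of this overlap may come from them, and no value without an effect was computed for it. The count of 116 depended on the model and on the number of libraries. With only the 4 groups compared in the model it was 544, with all 116 among them. In the model of all 6 groups, the omission of any 1 of the 12 libraries moved it. Without WT_DMSO_medium library 1, 2 or 3 it was 68, 37 or 1512, and without WT_DMSO_TL8 library 1, 2 or 3 it was 52, 32 or 32. Without WT_H151_medium library 1, 2 or 3 it was 29, 40 or 35, and without WT_H151_TL8 library 1, 2 or 3 it was 36, 32 or 33. It was 15 without libraries 1 and 2 of WT_DMSO_medium together, and its upward share went from 26.7% to 38.5% after rescaling by the upper quartile.

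H151 alone, in medium, raised genes of the oxidative stress response. HMOX1, the haem oxygenase, went from 24.3 ± 4.73 to 349 ± 41.1 (SD, n = 3; log2 fold change 3.80 ± 0.36, limma adjusted p = 5.56e-07). TRIM16L went from 53 ± 13.5 to 351 ± 18.5 (2.73 ± 0.14, limma adjusted p = 6.27e-11) and OSGIN1 from 51.7 ± 10.7 to 320 ± 23.5 (2.62 ± 0.31, limma adjusted p = 4.76e-06). Of 29 NRF2 genes, 20 rose, 2 fell and 7 did not pass (21 and 2 adjusted over the list alone; median 0.59, camera adjusted p = 2.93e-11, lost with an estimated correlation at adjusted p = 0.145). The long non-coding RNA LUCAT1 (2.92 ± 0.40), the transcription factor gene MSC (2.65 ± 0.18) and the growth factor receptor gene CSF1R (1.13 ± 0.11) rose. The long non-coding RNA DANCR (-1.25 ± 0.08), SUMF1 (-1.03 ± 0.11) and ODC1, the first enzyme of polyamine synthesis (-0.99 ± 0.08), fell (limma adjusted p of 2.63e-05 or lower).

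Part of the proliferation genes was lower with H151. Of 38 proliferation genes, 18 fell, 2 rose and 18 did not pass (19 and 3 adjusted over the list alone; median -0.15, camera adjusted p = 4.55e-06, lost with an estimated correlation at adjusted p = 0.145). GINS2, PCNA and MCM6, parts of the replication machinery, fell by 0.76, 0.66 and 0.57 on the log2 scale (limma adjusted p from 1.05e-06 to 1.18e-05). The topoisomerase gene TOP2A did not pass (-0.13 ± 0.06, limma adjusted p = 0.143). Of 35 ribosomal protein genes, 31 fell and 4 did not pass (34 adjusted over the list alone; median -0.35, camera adjusted p = 6.82e-11, lost with an estimated correlation at adjusted p = 0.587). Without WT_DMSO_medium libraries 1 and 2 together this median was -0.089 (camera adjusted p = 0.0271). The share of ribosomal protein genes was 7.17% to 7.41% in the H151 medium libraries and 9.11%, 10.1% and 7.62% in the DMSO medium libraries 1, 2 and 3. Interferon-stimulated genes went both ways in medium, with 12 of 58 higher, 6 lower and 40 not past the test (12 and 6 adjusted over the list alone; median 0.03, camera adjusted p = 0.833), IFIT1 at -1.28 ± 0.22 (limma adjusted p = 0.000176) and STAT2 at 0.82 ± 0.09 (limma adjusted p = 1.12e-06). TMEM173 was higher with H151 (0.20 ± 0.06, limma adjusted p = 0.0216), a call lost without WT_DMSO_medium library 2 (0.106) or WT_H151_medium library 1 (0.0531), 2 (0.0549) or 3 (0.0674), or without WT_DMSO_medium libraries 1 and 2 together (0.131). In medium, H151 changed 5031 genes, 2562 upward and 2469 downward. The count was 3227 without WT_DMSO_medium library 2 and 1203 without libraries 1 and 2 together. The authors' deposited table counts 5769 genes for these groups.

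With TL8 present, H151 again raised the oxidative stress genes, and a part of the interferon-stimulated genes was lower. HMOX1 was 233 ± 22.0 with TL8 and 3441 ± 224 with H151 and TL8 (SD, n = 3; 3.88 ± 0.36, limma adjusted p = 1.96e-07). Of 29 NRF2 genes, 25 rose and 4 did not pass (25 adjusted over the list alone; median 0.94, camera adjusted p = 5.21e-27 and, with an estimated correlation, adjusted p = 0.00959), with TRIM16L at 2.20 ± 0.14 and the transporter gene ABCC3 at 2.19 ± 0.48. Thioredoxin, TXN, did not pass the test (0.20 ± 0.12, limma adjusted p = 0.273, but 0.0163 with only the groups compared in the model). LUCAT1 rose by 2.66 ± 0.40 and the endothelin receptor gene EDNRB by 2.94 ± 0.51 (limma adjusted p of 0.000315 or lower). The chemokine genes CXCL9 (-1.66 ± 0.42, limma adjusted p = 0.00693), CXCL11 (-1.31 ± 0.20, limma adjusted p = 8.15e-05) and CCL2 (-1.01 ± 0.16, limma adjusted p = 9.61e-05) were lower.

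**Figure D3:**
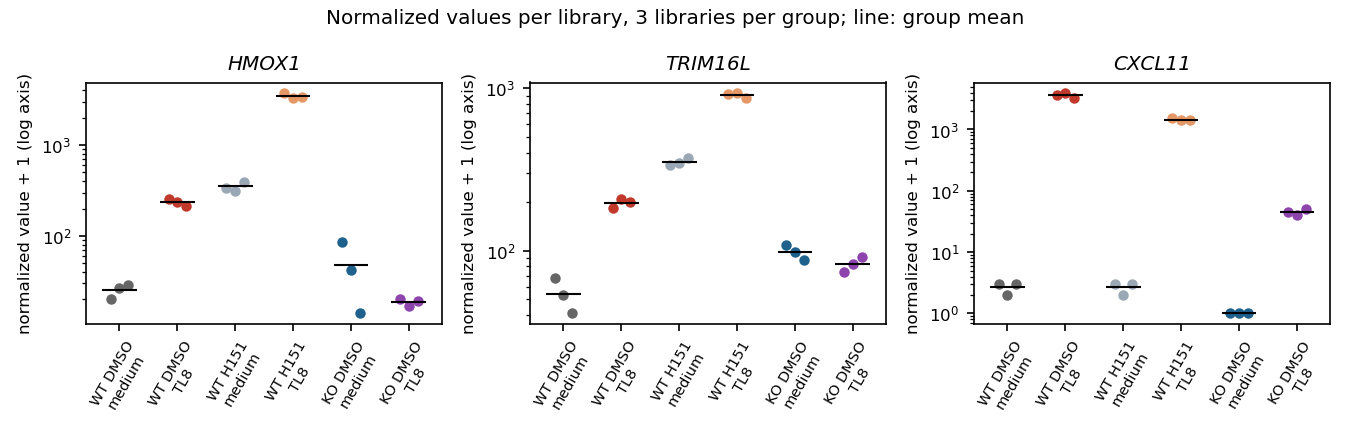
Normalized value + 1 per library (points, log axis) of HMOX1, TRIM16L and CXCL11 in the 6 groups, with 3 libraries each and a line at the group mean. HMOX1 was at 24.3 and 349 in wild-type cells in medium without and with H151, and at 233 and 3441 with TL8.

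CXCL10 was 33196 ± 2554 with TL8 and 14368 ± 939 with H151 and TL8 (SD, n = 3; -1.21 ± 0.37, limma adjusted p = 0.0232), a call lost without WT_DMSO_TL8 library 1 (0.0675) or 2 (0.0721) or WT_H151_TL8 library 1 (0.0529), 2 (0.0644) or 3 (0.0699), and also without limma's trend (0.0698) or with a pseudocount of 0.5 (0.103). The libraries themselves did not overlap, at 34487, 34847 and 30254 against 15366, 14236 and 13501. Its SE comes from the spread over all 6 groups, which include wild-type medium groups near the floor (0, 1 and 0 with DMSO and 3, 0 and 0 with H151). CXCL8 was higher with H151 (1.17 ± 0.36, limma adjusted p = 0.0226), a call lost without any 1 of the 6 libraries compared (limma adjusted p from 0.0503 to 0.0676). IFIT1 (-0.51 ± 0.22, limma adjusted p = 0.0998) and ISG15 (-0.32 ± 0.14, limma adjusted p = 0.119) did not pass, though both did with only the groups compared in the model (1.36e-06 and 0.00124). Of 58 interferon-stimulated genes, 12 fell and 46 did not pass (12 adjusted over the list alone; median -0.22, camera adjusted p = 8.25e-06, lost with an estimated correlation at adjusted p = 0.138). Of 38 proliferation genes, 20 fell, 2 rose and 16 did not pass (22 and 5 adjusted over the list alone; median -0.24, camera adjusted p = 2.73e-07, lost with an estimated correlation at adjusted p = 0.0768), with GINS2 at -0.64 ± 0.08, MCM7 at -0.60 ± 0.06 and the transcription factor gene E2F1 at -0.55 ± 0.07. Of 35 ribosomal protein genes, 0 passed with limma (0 adjusted over the list alone), at a median of -0.04. In total 3408 genes changed, 1658 upward and 1750 downward. The upward share was 48.7% and, after rescaling by the upper quartile, 60.1%. The authors' deposited table counts 4190 genes. Of the genes that rose with H151 in medium, 974 of 2562 also rose with H151 under TL8, where independent lists would share 259.4. Similarly, 1066 of 2469 that fell in medium also fell, against 263.9.

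The knockout line differed from the wild type in medium in many genes. SPARC, a matrix glycoprotein, was 1.33 ± 0.577 in wild-type cells and 1044 ± 101 in knockout cells (SD, n = 3; log2 fold change 8.83 ± 0.44, limma adjusted p = 4.24e-13). VSIG4, a complement receptor of macrophages, was 4.67 ± 2.52 and 407 ± 13.3 (6.28 ± 0.34, limma adjusted p = 1.74e-12). SPINK4 (7.46 ± 0.36) and the urea cycle gene CPS1 (6.07 ± 0.30) were also higher. The small heat shock protein gene HSPB7 (-7.23 ± 0.33), the death receptor gene TNFRSF25 (-6.88 ± 0.33), LIN7A (-6.79 ± 0.25) and the epoxide hydrolase gene EPHX2 (-6.45 ± 0.34) were lower (limma adjusted p of 9.6e-13 or lower). Of 58 interferon-stimulated genes, 40 were lower, 7 higher and 11 not past the test (40 and 7 adjusted over the list alone; median -0.70, camera adjusted p = 3.57e-06, lost with an estimated correlation at adjusted p = 0.0815). RSAD2 (-3.88 ± 0.45), IFI6 (-3.28 ± 0.28), SIGLEC1 (-2.68 ± 0.19) and ISG15 (-1.60 ± 0.14) were lower and CXCL10 was higher (2.48 ± 0.37), with limma adjusted p of 5.45e-06 or lower. Among the panel of cytokines, TNF was lower (-1.62 ± 0.23, limma adjusted p = 2.49e-06) and CXCL8 (2.61 ± 0.36, limma adjusted p = 1.81e-06) and IL1B (1.41 ± 0.31, limma adjusted p = 0.000531, but 0.90 without STINGKO_DMSO_medium library 1) higher.

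Receptor pathway genes differed before any stimulus. TLR7 was lower in the knockout line in medium (-2.29 ± 0.43, limma adjusted p = 8.48e-05) and TLR4 higher (2.47 ± 0.10, limma adjusted p = 3.43e-14). The values of TLR7 were near the floor, at 4, 0 and 0 in the knockout and 8, 4 and 12 in the wild type. TLR8 was lower at 4.33 ± 1.53 against 1.00 ± 1.00 (-1.51 ± 0.48, limma adjusted p = 0.00987), a call lost without STINGKO_DMSO_medium library 2 (0.0699), without WT_DMSO_medium libraries 1 and 2 together (0.083) or with a pseudocount of 8 (0.0698). Of 26 genes of this pathway, 6 were higher, 13 lower and 7 not past the test (6 and 13 adjusted over the list alone; median -0.13, camera adjusted p = 0.501). UNC93B1, the chaperone that carries endosomal Toll-like receptors out of the endoplasmic reticulum and a gene chosen here after its values were seen, was 2085 ± 104 in the wild type and 789 ± 43.0 in the knockout (SD, n = 3; -1.40 ± 0.07, limma adjusted p = 1.37e-13). Of 26 monocyte to macrophage marker genes, 6 were higher, 13 lower and 7 not past the test (6 and 13 adjusted over the list alone; median -0.56, camera adjusted p = 0.0515), with the proteoglycan gene VCAN at -4.94 ± 0.17 and the scavenger receptor gene MSR1 at 14 ± 1 in the wild type and listed at 0 in the knockout.

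Cholesterol synthesis genes were higher in the knockout line, 19 of 23 with 1 lower and 3 not past the test (20 and 1 adjusted over the list alone; median 0.73, camera adjusted p = 1.79e-07 and, with an estimated correlation, adjusted p = 0.0231). SQLE (1.61 ± 0.05), HMGCS1 (1.49 ± 0.06) and DHCR7 (1.47 ± 0.11) led this list (limma adjusted p of 2.32e-10 or lower). Of 11 liver X receptor targets, 6 were higher, 1 lower and 4 not past the test (6 and 1 adjusted over the list alone; median 0.75, camera adjusted p = 0.0332, lost with an estimated correlation at adjusted p = 0.0815), with the cholesterol exporter gene ABCG1 at 3.95 ± 0.37. Histone and mitochondrially encoded genes also differed with the genotype. Of 16 replication-dependent histone genes, whose transcripts lack a poly(A) tail and have near-identical copies, 15 were higher and 1 not past the test (15 adjusted over the list alone; median 1.39, camera adjusted p = 0.000126 and, with an estimated correlation, adjusted p = 0.0231), with HIST1H2BJ at 3.16 ± 0.25 and HIST1H1C at 2.96 ± 0.11. The cause of the histone rise was not tested. Of 38 proliferation genes, 22 were higher, 7 lower and 9 not past the test (23 and 7 adjusted over the list alone). Their median was 0.22 (camera adjusted p = 0.0515). The mitochondrially encoded share was 4.62% to 6.71% of the values in knockout libraries in medium and 3.62% to 4.67% in wild-type libraries in medium. In medium 10195 genes differed, 4965 higher and 5230 lower in the knockout line, with 968 and 2023 at least 2-fold. The authors' deposited table counts 10484.

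With TL8 the distance between the lines was larger in interferon-stimulated genes. All 58 were lower in the knockout line (58 adjusted over the list alone; median -4.40, camera adjusted p = 1.33e-33 and, with an estimated correlation, adjusted p = 0.000394). IFI44L was 13904 ± 385 in the wild type and 18.3 ± 5.51 in the knockout (SD, n = 3; -9.54 ± 0.50, limma adjusted p = 5.11e-13). IFI27 was 1320 ± 89.6 and 3.00 ± 3.61 (-8.84 ± 0.50, limma adjusted p = 1.54e-12) and the receptor tyrosine kinase gene AXL 3411 ± 44.6 and 4.33 ± 2.89 (-9.53 ± 0.51, limma adjusted p = 7.44e-13). CXCL10 differed by -5.68 ± 0.37, IFIT1 by -5.33 ± 0.22, ISG15 by -4.95 ± 0.14 and RSAD2 by -7.82 ± 0.45 (limma adjusted p of 1.69e-11 or lower). Of 22 antigen presentation genes, 20 were lower and 2 not past the test (20 adjusted over the list alone; median -1.19, camera adjusted p = 3.41e-07 and, with an estimated correlation, adjusted p = 0.0176), with HLA-F at -6.33 ± 0.36, a gene whose reads can be shared within its family. UNC93B1 (-2.71 ± 0.07), TLR7 (-4.71 ± 0.43), CCL2 (-5.11 ± 0.16) and ICAM1 (-4.25 ± 0.48) were lower. Of the 16 histone genes, 15 were higher and 1 not past the test (16 adjusted over the list alone; median 1.39, camera adjusted p = 0.000177 and, with an estimated correlation, adjusted p = 0.0194). SPARC (9.33 ± 0.44) and VSIG4 (6.79 ± 0.34) were again higher. In total 11171 genes differed, 5347 higher and 5824 lower in the knockout line. The authors' deposited table counts 11481.

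Both interactions were compared across genes, which are not independent replicates. The log2 fold changes of the knockout and H151 interactions correlated at 0.47. The correlation was 0.502 on average over 100 simulated draws in which neither arm had an effect, because both are taken against the same 6 wild-type DMSO libraries. The covariance was 0.130 against a simulated 0.0484, a difference of 0.0819. Lower in both were 80 genes and higher in both 21, where independent lists would share 12 and 3.23. The draws shared 0 and 0, which gives no reference, since few genes can pass where neither arm has an effect. A further 5 genes went opposite ways. With 3 shared libraries per group, no part of them keeps 2 libraries on each side, so part of this excess may come from the shared controls.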

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

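The tests of explanations here were chosen after the results were seen, except the counts over other splits of the libraries, which were planned. The results listed are differences between the TL8 responses of groups, each tested as an interaction. With the knockout, 4023 genes differed. The medians of the lists were -3.26 for interferon-stimulated genes, -1.76 for inflammatory cytokines and chemokines, -0.94 for NF-kappaB genes, -0.21 for the endosomal Toll-like receptor pathway, -0.79 for antigen presentation, -0.37 for NRF2 genes, -1.07 for the unfolded protein and integrated stress responses, -0.33 for cholesterol synthesis and 0.35 for ribosomal proteins. With an estimated correlation the calls of NRF2 genes (camera adjusted p = 0.121), cholesterol synthesis (camera adjusted p = 0.0979) and ribosomal proteins (camera adjusted p = 0.502) were lost. The WT_DMSO_medium libraries, which enter both interactions, differed in the share of ribosomal protein genes, at 9.11%, 10.1% and 7.62% in libraries 1, 2 and 3.

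Among named genes the knockout differences were 0.37 for TMEM173, -8.16 for CXCL10, -4.37 for IFIT1, -3.35 for ISG15, -2.41 for MX1, -3.94 for RSAD2, -1.40 for TNF, -2.80 for IL1B, -3.44 for CXCL8, -0.85 for NFKBIA, -8.92 for GBP1, -8.72 for IFI44L, -8.78 for IGFBP3 (-7.34 without STINGKO_DMSO_medium library 1 and -10.76 without library 3), -6.53 for CCL2, -7.14 for TNFAIP6, -4.37 for ICAM1, -1.95 for ATF3, -1.71 for HYOU1, -2.95 for TAP1, -2.98 for HLA-F, -4.21 for HMOX1 (-3.60 and -4.91 without the same libraries), -2.12 for MYD88, 2.75 for SERPINB2, 1.87 for WNT7B, 1.77 for DEPTOR and 1.64 for NFE2. The differences of IL1B, CXCL8, TNFAIP6 and ICAM1 also rest on knockout libraries in medium that varied in these genes. With H151, 116 genes differed, and the list medians were -0.27 for interferon-stimulated genes, -0.16 for NF-kappaB genes, -0.14 for antigen presentation, 0.31 for NRF2 genes, 0.11 for heat shock genes and 0.29 for ribosomal proteins. None of these 6 calls held with an estimated correlation (camera adjusted p of 0.172 for the first and 0.453 for the other 5). The gene differences with H151 were -1.31 for CXCL11, -0.86 for SAMD9L, -0.85 for GBP4, -1.28 for CD209, -1.15 for C3AR1, -0.99 for GBP2, -2.81 for RN7SL2, 0.80 for ARRDC4, 0.74 for SERPINB2 and 0.69 for SLC7A11, and those that rest on single libraries are named with their values in the report. The differences of SAMD9L, GBP4, CD209, C3AR1, GBP2 and SERPINB2 came in part or in whole from medium values that differed with H151.

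Of 100 splits of the same 12 libraries, the real one included, 13 gave as many genes as the 4023 of the knockout interaction, with 12165 as the highest of the others. For the 116 of the H151 interaction it was also 13 of 100 with the real one included, with 6143 as the highest of the others. By that count chance was not excluded for either. In each, the 12 other splits as large let the difference between the arms into the interaction, so the count cannot decide about chance. In 29 splits for the knockout and 38 for H151, the real one included, that difference cancels, a choice made after the result was seen. None but the real one was as large there (68 and 0 genes as the highest of the others). Every other such split mixes both arms within its groups, which adds their difference to the spread and leaves few genes to call. This count therefore decides nothing either.

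The pattern weighed here is the smaller TL8 response of the knockout line in the interferon-stimulated and NF-kappaB lists. If the line scaled the log2 responses of both lists equally, the slope of the knockout response on the wild-type response would be the same in both. The slopes were 0.310 and 0.495, a difference of 0.185 (two-sided permutation p = 0.00307, 100000 permutations of list membership over genes). This goes against equal scaling alone. The permutation treats genes of 1 line as independent, although members of a list can move together. A lower responsiveness that acts unequally on the lists stays open. Lower expression of the endosomal receptor pathway stays open. UNC93B1, chosen after its values were seen, was at -1.40 in the knockout line in medium, which is confounded with the genotype. With 1 knockout line, a low UNC93B1 could only leave this open. The 26 genes of the pathway were not called as a list there, with 6 higher, 13 lower and a median of -0.13 (camera adjusted p = 0.501). Loss of STING stays open too, as the H151 interaction had a list median of -0.27 in the same direction, far from -3.26, and lost its call with an estimated correlation. A single knockout line with many other differences cannot separate STING from other properties of that line, and how far H151 blocked STING was not measured here.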

How the results depend on the processing

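Of 3022 combinations of a named gene result and an alternative, 2869 kept their side of the threshold without a turn of a called value, 93 lost the call, 9 gained it and 51 turned direction with a call before or after. Of the 2869, 2860 kept their sign and 9, from 6 results, were not called either way and changed it. These 9 were CCL22 (rescaled, without WT_DMSO_medium library 2, and without libraries 1 and 2) and HLA-DRB1 (the last 2 of these) for TL8 in wild-type cells, MX1 and IFI44L without STINGKO_DMSO_medium library 3 and RSAD2 with a pseudocount of 8 for TL8 in knockout cells, and ISG15 in the H151 interaction without WT_DMSO_medium libraries 1 and 2. Of the 51, 50 came from the title and treatment labels, which exchange the wild-type group with DMSO and TL8 and that with H151 and medium, so the exchange itself is the cause. The other of the 51 was RSAD2 with TL8 in the knockout line without STINGKO_DMSO_TL8 library 2 (0.75, limma adjusted p = 0.00184). Its log2 fold change ranged from -0.84 to 0.75 when 1 library was left out, and the cause was not tested.

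Under the title and treatment labels the counts were 5031 for TL8 in wild-type cells, 3408 for TL8 with H151, 7680 for H151 in medium and 5953 for H151 with TL8, and the median knockout interaction of interferon-stimulated genes turned to 1.02 (camera adjusted p = 1.35e-24). Of the 931 genes that rose with TL8 in the knockout line, which the exchange leaves as it is, 812 rose in the group described as DMSO and TL8 (223.4 for independent lists) and 244 in the group described as H151 and medium (145.7 for independent lists). These values go against the exchange, as it needs the latter group to be the one with TL8. The log2 fold changes that turned were, for TL8 in wild-type cells, TMEM173 0.20, TLR8 -0.21, MYD88 -0.052, IFIT1 -1.28, ISG15 -0.47, IFI44L -0.35, IL1B -0.93, NFKBIA -0.12, CCL2 -0.075, METTL7A 0.56, DEPTOR 0.28 and ALPP -0.055. For the knockout interaction they were TMEM173 -0.17, TLR8 2.05, CXCL10 6.19, IFIT1 5.45, ISG15 1.96, TNF 2.39, IL1B 4.01, CXCL8 1.12, NFKBIA 2.67, IFI44L 0.59, CCL2 1.94, ICAM1 2.40, ATF3 0.33, ATF4 0.35, TAP1 0.82, MYD88 0.58, WNT7B -0.29, DEPTOR -0.69 and NFE2 -0.29. For TL8 with H151 they were CXCL10 -1.21, IFIT1 -0.51, CCL8 -0.57 and TRIM22 -0.16, and for H151 in medium TMEM173 -0.34 and IFIT1 8.53. For the knockout with TL8 they were CXCL10 8.67, ISG15 0.36, IFIT1 4.49, TLR7 0.50, CCL2 3.37 and ICAM1 2.51, and for H151 with TL8 CXCL9 5.92, CXCL10 13.14, CXCL11 9.11, CCL2 7.46, IFIT1 9.30, ISG15 4.99 and E2F1 0.039.

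A minimum absolute log2 fold change of 1 left 1759 genes for TL8 in wild-type cells, 356 for TL8 in knockout cells, 1056 for the knockout interaction, 1434 for TL8 with H151, 9 for the H151 interaction, 257 for H151 in medium, 2991 and 3850 for the knockout in medium and with TL8, and 215 for H151 with TL8, by its construction. With only the groups compared in the model, TL8 in knockout cells gave 767 genes, the H151 interaction 544 and H151 with TL8 5339. The H151 interaction gave 35 genes without limma's trend and 57 with no filter. Leaving out WT_DMSO_medium libraries 1 and 2 together, added after seeing the data, gave 4865 genes for TL8 in wild-type cells, 2190 for the knockout interaction, 15 for the H151 interaction and 1203 for H151 in medium, where fewer samples are part of the cause. For the other changes in this paragraph the cause was not tested. With an estimated correlation 34 of 180 list tests were called in place of 75, and the median of -0.27 of interferon-stimulated genes in the H151 interaction lost its call (camera adjusted p = 0.172).

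Leaving out 1 library at a time, with the shared spread of all groups, gave 6408 to 8037 genes for TL8 in wild-type cells, 1066 to 2116 for TL8 in knockout cells, 3169 to 5210 for the knockout interaction, 4854 to 5226 for TL8 with H151, 29 to 1512 for the H151 interaction, 3227 to 5949 for H151 in medium, 9452 to 10003 and 10470 to 10822 for the knockout in medium and with TL8, and 2402 to 2734 for H151 with TL8. The median of interferon-stimulated genes lay between -3.33 and -2.94 in the knockout interaction and between -0.32 and -0.22 in the H151 interaction. The replicate number as a block gave 7736, 1507, 4011, 5972, 116, 5095, 10250, 11201 and 3479 genes for TL8 in wild-type cells, TL8 in knockout cells, the knockout interaction, TL8 with H151, the H151 interaction, H151 in medium, the knockout in medium, the knockout with TL8 and H151 with TL8. The numbers showed no full pairing of the samples, since 0 of 15 pairs of groups had every correlation of same-numbered deviations above 0.1 (range -0.189 to 0.216) and in 0 pairs did all 6 libraries correlate best with their own number. A weak or partial pairing is not excluded by this rule. The correlation of both interactions was 0.47 over all genes, 0.50 over genes called in a wild-type TL8 response and 0.47 with the block. Rescaling by the weighted trimmed mean was not run, since the upper quartile was used. IFNB1 lies below the filter. With no filter it was at 1.97 for TL8 in wild-type cells (limma adjusted p = 0.00321), 0.33 for TL8 in knockout cells (limma adjusted p = 0.858) and -2.16 for the knockout with TL8 (limma adjusted p = 0.000714). The knockout interaction, at -1.64, did not pass (limma adjusted p = 0.142). With H151 it was at 1.06 for TL8 (limma adjusted p = 0.145), -0.91 for the H151 interaction (limma adjusted p = 0.678) and -1.44 for H151 with TL8 (limma adjusted p = 0.0616).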

Other observations

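All tests of explanations below were chosen after the results were seen, and the counts over other splits of the libraries were planned. Genes of cytosolic nucleic acid sensing went both ways with TL8 in wild-type cells, with 8 of 21 higher, 7 lower and 6 not past the test (10 and 7 adjusted over the list alone; median log2 fold change 0.16, camera adjusted p = 0.0547). NRF2 genes rose, 22 of 29 with 7 not past the test (22 adjusted over the list alone; median 0.49, camera adjusted p = 4.74e-07, lost with an estimated correlation at adjusted p = 0.109), and with H151 present TL8 raised 28 of 29 (28 adjusted over the list alone; median 0.85, camera adjusted p = 4.47e-15 and, with an estimated correlation, adjusted p = 0.014). Cholesterol synthesis genes rose with TL8 in both lines. In the wild type 18 of 23 rose, 2 fell and 3 did not pass (18 and 2 adjusted over the list alone; median 0.48, camera adjusted p = 8.25e-07 and, with an estimated correlation, adjusted p = 0.0136), and in the knockout 10 rose and 13 did not pass (15 adjusted over the list alone; median 0.24, camera adjusted p = 4.61e-08 and, with an estimated correlation, adjusted p = 0.00937). Of 35 ribosomal protein genes, 16 were lower in wild-type cells with TL8 and 19 not past the test (18 adjusted over the list alone; median -0.26, camera adjusted p = 0.000295, lost with an estimated correlation at adjusted p = 0.627). The DMSO medium libraries they are compared with differ in these genes, with shares of 9.11%, 10.1% and 7.62% in libraries 1, 2 and 3.

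Among the other lists in wild-type cells with TL8, 9 of 22 glycolysis genes rose and 3 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.0487, lost with an estimated correlation at adjusted p = 0.323), 10 of 20 p53 targets rose and 6 fell (10 and 6 adjusted over the list alone; camera adjusted p = 0.137), and 5 of 16 heat shock genes rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.363). Of 13 mitochondrially encoded genes, 8 were higher in the knockout line in medium and 5 not past the test (9 adjusted over the list alone; median 0.50, camera adjusted p = 0.0515). Markers of other cell types differed between the lines in medium in both directions. Of 8 measured lymphoid markers, 3 were higher, 2 lower and 3 not past the test (3 and 2 adjusted over the list alone; camera adjusted p = 0.71), of 7 epithelial and fibroblast markers, 1 was higher, 4 lower and 2 not past the test (1 and 4 adjusted over the list alone; camera adjusted p = 0.501), and of 2 erythroid and megakaryocyte markers, 1 was higher and 1 not past the test (1 adjusted over the list alone), with no camera test on so short a list.

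The 3 knockout libraries in medium differed in some of the genes that TL8 raises in wild-type cells, a pattern and genes picked after their values were seen. ALPP was at 4680, 1514 and 195 in libraries 1, 2 and 3, IGFBP3 at 112, 31 and 0, CXCL8 at 368, 154 and 61, HMOX1 at 85, 41 and 13 and IL1B at 140, 64 and 35. Other genes that TL8 raises there did not follow it, with CCL2 at 53, 46 and 49, MYD88 at 927, 916 and 919 and C3AR1 at 107, 103 and 127. RNA of TL8-treated knockout cells in library 1 would have to make up 27.3% of it to give its ALPP, while the 27 interferon-stimulated genes that TL8 raised at least 2-fold in that line need a median of 6.73% (range 0 to 46.6%) and the 15 NF-kappaB genes 8.93% (range 0 to 34.7%). Lower than 27.3% were 24 of the 27 and 13 of the 15, but the ranges hold it, and only 4 of the 27 and 5 of the 15 lie in whole under what it would bring, by more than 3 square roots of their value. IGFBP3 and HMOX1 are not raised by TL8 in the knockout line, where they were at 1, 0 and 0 and at 19, 16 and 18 with TL8. Their 112 and 85 in library 1 lie above the highest value of a source by a ratio of at least 4.47, which argues against this source for both and so as the whole cause. It stays open for ALPP, CXCL8 and IL1B. RNA of TL8-treated wild-type cells would have to make up 3.27%, while the 51 interferon-stimulated genes at 1000 or more in those cells need a median of 0.226% (range 0 to 7.25%). Of the 51, 49 need less than 3.27%, and in 32 the whole value in library 1 lies under what 3.27% would bring, by more than 3 square roots of it, which argues against that source. An earlier form of that test on 5 wild-type genes gave a median of 2.12% with a range of 0.314% to 4.27% and decided nothing. No biological explanation was tested, since the labels give these 3 libraries no difference.

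ALPP, which encodes placental alkaline phosphatase, rose with TL8 in wild-type cells from 667 to 137506, a log2 fold change of 7.68 ± 0.60, and its neighbour ALPG from 16 to 2933 (7.44 ± 0.74). Both were singled out after their values were seen. The values that shared reads would need are there, as ALPG stood at 1.80 to 2.55 per 100 of ALPP in the 6 groups, a ratio of 1.42 between the highest and the lowest, so the rise of ALPG may be reads of ALPP. Transcripts of a reporter gene carried by the line stay open as a source of the 7.68, because reads of a reporter and of the cell's own gene cannot be told apart in a table of gene values. The labels do not say which phosphatase sequence the reporter holds.

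Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. All but the real one mix both groups, which adds their difference to the spread and lowers the counts. The real split gave 7680 genes for TL8 in wild-type cells against 0 as the highest of the others, 1497 against 8 for TL8 in knockout cells, 5953 against 0 for TL8 with H151, 5031 against 0 for H151 in medium, 10195 against 830 for the knockout in medium, 11171 against 0 for the knockout with TL8 and 3408 against 1 for H151 with TL8, and in each 1 of 10 splits, the real one, was as large.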
